A study of Chlamydomonas reinhardtii with 6 samples.

How the data were processed

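The series holds 6 RNA-seq libraries of Chlamydomonas reinhardtii, 3 WT and 3 cmd1 KO, all from cells exposed to high light. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded total RNA kit. The length of the exposure is not given in the sources used here. Groups and replicate numbers were taken from the sample titles, which the labels' protocols describe as biological replicates.

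Per the submitters' processing notes, the tools included FastQC 0.11.5, TopHat2 and Cufflinks 2.0.0. The genome build, the strand setting and the tool that counted reads are not given in the sources used here. The deposited counts are whole-number read counts per gene, not normalised, per the file headers. The deposited FPKM values, named so per the file headers, equalled the count divided by a fixed length per gene and by the column total. The implied lengths were whole numbers for 100% of genes within a tolerance of 0.01 base, with a median of 2608 bases, so the FPKM columns carry no scaling beyond library size. The deposited log2 fold changes and log2 CPM, the deposited F statistic (a score per gene) and the deposited unadjusted p-value come from the authors' own comparison of cmd1 KO with WT, per the file headers. No header states their model. The authors' model was sought by fitting 6 edgeR models to all 17736 genes, of which the one with library sizes alone and a term for replicate 3 matched the deposited values. All rows carried a gene identifier, and 0 columns of per-sample values were left unused.

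Of the 17736 identifiers, 17733 matched the RefSeq gene table of the v5.5 assembly by locus tag. The identifiers carry the same v5.5 suffix, so its coordinates were used. That table gives 0 symbols other than locus tags and the files do not pair identifiers with names. CMD1, the photoprotection genes named beforehand and the 26 fixed gene lists (camera tests) were therefore not analysed here. The rule for named genes, set before the data were examined, took CMD1 and photoprotection genes, the 10 largest changes per direction past an adjusted p of 0.05, list members, and at most 2 unnamed identifiers per direction past 0.05. No gene passed, so the 4 identifiers printed are the 2 per direction with the smallest p among genes whose groups did not overlap, chosen after their values were seen. Genes that overlap or share reads with near-identical copies were not separated here, so single gene values can include reads of a relative.

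The design fixed before the data were examined foresaw limma on log2(FPKM + 1), or edgeR should the table hold raw counts. It did, so the main test was edgeR 4.0.16 (glmQLFit and glmQLFTest, two-sided) on the counts, with TMM factors, genotype as the only term, and Benjamini-Hochberg adjustment over genes with a mean of at least 1 FPKM over the 6 libraries. limma 3.58.1 and DESeq2 1.42.0 (268 adjusted p-values left as NA) were run as alternatives, in R 4.3.3. Log2 ratios per same-numbered pair used log2 CPM with a prior count of 1. Also set before the data were examined were the FPKM filter, pseudocounts, scalings of the FPKM, limma variance models, the replicate block, leaving out each library, the edgeR fit on all 10 splits of the 6 libraries into 3 and 3, and the adjusted p thresholds. Chosen after the data were seen were the fit within replicates 1 and 2, the interaction test, the counts of genes near 0 between WT replicates, the shares of genes without overlap in other splits, the paired permutation tests, the term for replicate 3, the other edgeR scalings, the most abundant genes and their ranking on WT alone, the share of WT kept by the core genes of the chromosome 17 block under each scaling and the bound on it, the length classes, the near-zero rules and the chromosome scan. Per-library values were compared by exact permutation tests in scipy 1.17.1 under Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

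The replicate numbers were checked for pairing. The correlation of same-numbered libraries' deviations from their group means was 0.530, 0.427 and 0.547 for numbers 1, 2 and 3. Numbers 1 and 2 were not told apart, since WT replicate 2 correlated at 0.479 with cmd1 KO replicate 1, and WT replicate 1 at 0.491 with cmd1 KO replicate 2. The check therefore shows a shared shift in replicate 3 only. The labels list the replicates as WT and mutant together by number, and the pairing of numbers 1 and 2 rests on that listing alone. Counts of different libraries differed by more than sampling noise. The chi-square per degree of freedom was 26.4 for WT replicates 1 and 2, 12.2 for cmd1 KO replicates 1 and 2 and 123 for the libraries of replicate 3. This shows only that no 2 columns hold the same library counts, and the 6 were treated as separate replicates because the labels call them biological replicates. Principal component 1 held 63.0% and component 2 held 29.6% of the variance of the log2 CPM. On component 1, cmd1 KO replicates 1 and 2 lay at 93.5 and 103, and the other libraries between -84.7 and -12.6. On component 2, WT replicates 1 and 2 lay at 67.9 and 75.6, and the other libraries between -51.1 and -24.4.

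The chromosome scan took the 10776 tested genes on the 17 chromosomes, removed a loess trend on length (span 0.5), and compared running medians over 21 genes with the extremes of 1000 permutations of the gene order. Positions are 1-based. Depth ran from 38875025 to 47869886 counts per library. The p-values of the fits over all 6 libraries cover the spread between these cultures. Those of the fits within replicates 1 and 2 and of the interaction test cover only the smaller spread of replicates 1 and 2. The p-values of the scan come from permuted gene order and cover no spread between cultures. The edgeR and DESeq2 tests without a block, over 6 libraries and over 2 against 2, and the edgeR interaction test were tried on simulated data with 200 of 10878 genes changed. The simulated libraries varied independently around a common mean per gene, without the shared shift of replicate 3. The limma, replicate block and replicate 3 term fits were not simulated. With 6 libraries, edgeR recovered 0%, 0% and 87% of genes changed 2-fold, 4-fold and 16-fold. With 2 libraries against 2 at the spread of replicates 1 and 2, it recovered 79%, 99% and 100%, and the interaction test recovered 92% of 4-fold changes with 10 unchanged genes called. In a planted block of 25 genes, 22 of 22 windows found by the scan lay inside. The common biological coefficient of variation was 0.558 over all 6 libraries, 0.399 with the replicate block and 0.130 within replicates 1 and 2.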

Results

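Gene expression was measured by RNA sequencing in the unicellular green alga Chlamydomonas reinhardtii, in wild type (WT) cells and in a knockout of CMD1 (cmd1 KO), both in strain CC125. CMD1 is related to the TET dioxygenases, enzymes that oxidise the methyl group of 5-methylcytosine in animal DNA. The question was how loss of CMD1 altered gene expression. Cells were grown at 25 °C under 20 µmol photons per m2 per s in an acetate medium, moved to a high salt medium, and exposed to light of 300 µE. Each genotype had 3 biological replicates. The gene counts summed to 45087656, 41316097 and 39072635 in WT replicates 1, 2 and 3, and to 47869886, 39851299 and 38875025 in cmd1 KO replicates 1, 2 and 3, so the genotypes differed little in depth. The table covered 17736 gene models of the v5.5 annotation, of which 10878 had a mean of at least 1 FPKM and were tested. Neither the table nor the gene reference paired the identifiers with gene names, so the level of CMD1 itself and the 26 gene lists fixed beforehand were not analysed here, and genes are described by abundance, length and position.

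Within each same-numbered pair, counts were more concentrated in a small set of abundant genes in cmd1 KO, and the typical gene held fewer counts. Both differences were largest in replicates 1 and 2. The 50 most abundant genes, ranked by their mean share over all 6 libraries, took 62.1%, 61.8% and 34.3% of the counts in cmd1 KO replicates 1, 2 and 3, against 42.6%, 44.7% and 29.9% in the WT replicates of the same number. The share in cmd1 KO replicate 3 thus lay below those in WT replicates 1 and 2. It was not computed for a ranking on the WT libraries alone. The group means were 52.7% ± 15.9 (SD, n = 3) and 39.1% ± 8.01 (SD, n = 3), a difference of 13.6 percentage points (exact unpaired permutation test, two-sided, p = 0.3). The share was higher in cmd1 KO in all 3 same-numbered pairs, with an SD of 8.10 points between the paired differences (exact paired permutation test, two-sided, p = 0.25, the smallest that 3 pairs allow). The median count per gene was 117 ± 82.2 (SD, n = 3) in cmd1 KO and 273 ± 29.9 (SD, n = 3) in WT, and every cmd1 KO library lay below every WT library (exact permutation test, two-sided, p = 0.1). Genes with at least 10 counts numbered 14489 ± 422 (SD, n = 3) in cmd1 KO and 15441 ± 84.5 (SD, n = 3) in WT, and genes without a count 1490 ± 70.6 against 1189 ± 52.0 (exact permutation tests, two-sided, p = 0.1 for each). With 3 libraries against 3, no unpaired exact test can give a p under 0.1.

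**Figure D1:**
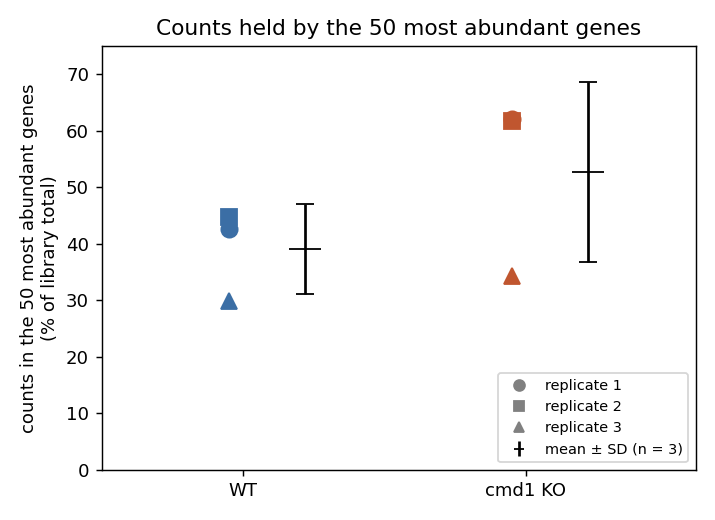
Percentage of each library's counts held by the 50 most abundant genes (vertical axis) in WT and cmd1 KO, with 1 symbol per library, the symbol's shape marking the replicate number, and black bars giving the mean ± SD (n = 3). The cmd1 KO symbols of replicates 1 and 2 lie at 62.1% and 61.8%, while that of replicate 3 lies at 34.3%, close to its WT partner at 29.9%.

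The 50 most abundant genes were short, with a median length of 842.5 bases, and 49 of them were higher in cmd1 KO in all 3 same-numbered pairs after trimmed mean of M-values (TMM) scaling. Their median log2 ratio was 1.88 in pair 1, 1.83 in pair 2 and 0.53 in pair 3. Scaling on library size alone lowered the log2 ratios of all tested genes by a median of 1.35, 1.41 and 0.31 in pairs 1, 2 and 3. It left 39 of the 50 genes higher in all 3 pairs, with medians of 0.52, 0.41 and 0.22. A ranking over all 6 libraries favours genes that are high in cmd1 KO replicates 1 and 2, whereas a ranking on the WT libraries alone does not. Of the 50 genes ranked on WT alone, 46 of them shared with the first ranking, 49 were higher in all 3 pairs with TMM scaling and 37 with library sizes alone. One by one, 25 of the 50 genes ranked over all 6 libraries had an unadjusted p under 0.05 in edgeR's quasi-likelihood test, and none passed after adjustment.

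Over all 6 libraries no single gene passed the main test for a genotype difference, while other tests and a smaller set of libraries gave many calls. edgeR's quasi-likelihood test found 0 of 10878 genes at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.263. Without cmd1 KO replicate 3 the same test called 1974 genes higher and 2255 lower. At an unadjusted p under 0.05 there were 994 genes higher and 958 lower in cmd1 KO with TMM scaling, and 46 higher and 1605 lower with library sizes alone. Pairing the replicate numbers in edgeR also gave 0 genes, with a smallest adjusted p of 0.18 and 2938 genes at an unadjusted p under 0.05. limma on log2(FPKM + 1) gave 0 genes, with a smallest adjusted p of 0.172 and 2795 genes at an unadjusted p under 0.05, and with array weights, whose estimation stopped before convergence, it gave 629 higher and 8487 lower. DESeq2 called 412 genes higher and 276 lower, and 633 of these 688, which were chosen for a group difference, had the same sign in all 3 pairs. In 528 of the 688 the size of the genotype effect differed between replicate 3 and replicates 1 and 2 in edgeR. Pairing the replicate numbers in DESeq2 gave 1082 genes higher and 790 lower. In 2506 genes the 3 cmd1 KO values all lay above or all below the 3 WT values, 1026 of them higher and 1480 lower, which is 23.0% of the tested genes. Chance gives 10% for 6 equally unlike libraries, but these were not, and the other splits of the 6 libraries gave 0.450% to 26.3%. The other 3 splits that part all 3 same-numbered pairs gave 12.2%, 0.634% and 0.827%. Simulated counts took the spread per gene from the main fit, but varied independently between libraries, whereas the real libraries of replicate 3 shifted together. On these counts edgeR recovered 0% of genes changed 4-fold and 87% of genes changed 16-fold, and called 0 and 8 unchanged genes. DESeq2 recovered 40% and 96.5% of the 200 changed genes and called 37 and 64 unchanged genes. At 2-fold DESeq2 recovered 0.5% and called 24 unchanged genes. In that setting its false calls ran above the share that an adjusted p of 0.05 allows, so its calls over all 6 libraries may be less certain than their adjusted p-values.

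Among genes whose genotypes did not overlap after TMM scaling, the 2 per direction with the smallest p differed several-fold. They were chosen after their values were seen, so the lack of overlap was a condition of the choice and not a result. All 4 had an adjusted p of 0.263 in edgeR, a value that many other genes shared. Cre01.g009350, on chromosome 1 from 1743156 to 1748134, stood at 26.8 ± 10.0 CPM (TMM-scaled, SD, n = 3) in cmd1 KO and 4.46 ± 1.08 in WT, a log2 difference of 2.59 (SE 0.41, adjusted p = 0.263 in edgeR). Cre11.g478100, on chromosome 11 from 2932083 to 2934444, stood at 39.4 ± 4.16 against 11.8 ± 0.758 CPM, a log2 difference of 1.74 (SE 0.28). Cre09.g411500, on chromosome 9 from 7059836 to 7064312, was at 2.83 ± 0.307 CPM in cmd1 KO and 9.92 ± 0.636 in WT, a log2 difference of -1.81 (SE 0.30). Cre08.g359567, on chromosome 8 from 581993 to 590495, was at 2.04 ± 0.702 against 9.81 ± 1.80 CPM, a log2 difference of -2.26 (SE 0.39). With library sizes alone the log2 differences of the 4 genes, in the order given, were 1.90, 0.92, -2.60 and -2.90, and the genotypes overlapped for Cre11.g478100, with WT replicate 3 at 21.2 CPM and cmd1 KO replicate 1 at 17.8. DESeq2 called all 4 genes, with adjusted p-values of 4.7e-07, 3.72e-08, 3.76e-05 and 0.000264. On simulated counts, though, DESeq2 called more unchanged genes than its threshold allows.

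The genotype difference was large and repeatable in replicates 1 and 2, and different in replicate 3. Across the 10878 genes, which are not independent replicates, the log2 ratios of pairs 1 and 2 correlated at r = 0.929 (Spearman 0.937), those of pairs 1 and 3 at 0.047 (0.202) and those of pairs 2 and 3 at 0.095 (0.235). The SD of the log2 ratios over genes was 1.37, 1.54 and 0.664 in pairs 1, 2 and 3. The libraries formed 3 sets: WT replicates 1 and 2, cmd1 KO replicates 1 and 2, and both libraries of replicate 3. Within these sets the libraries correlated at 0.9879, 0.9805 and 0.9548. Between sets, WT replicate 1 correlated at 0.7907 with WT replicate 3 and at 0.8093 with cmd1 KO replicate 1. The correlation of cmd1 KO replicate 1 with cmd1 KO replicate 3 was 0.6975. Within replicates 1 and 2, 2 libraries against 2, 3736 genes rose and 4117 fell in cmd1 KO at an adjusted p of 0.05 in edgeR, 4871 of them at least 2-fold. DESeq2 on those 4 libraries called 3714 higher and 3582 lower. With library sizes alone edgeR's split became 679 higher and 8610 lower, so the direction of many of these genes depended on the scaling. The genotype effect itself differed between replicate 3 and replicates 1 and 2 in 5510 genes (edgeR interaction test, adjusted p of 0.05), a test that takes the spread of the single replicate 3 library per genotype from replicates 1 and 2. That spread was small, with a biological coefficient of variation of 0.130 against 0.558 over all 6 libraries, so these counts are measured against it and not against the difference between cultures such as those of replicate 3.

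Gene length sorted the genotype difference in replicates 1 and 2. With TMM scaling, the shortest of 5 equal length classes of the tested genes, 241 to 1536 bases, had median log2 ratios of 0.87, 1.09 and 0.18 in pairs 1, 2 and 3, and the longest class, 3740 to 33247 bases, had -1.15, -1.36 and -0.10. Library sizes alone moved the shortest class below 0, to -0.48, -0.32 and -0.13, and the longest to -2.49, -2.77 and -0.41, with the order of the classes kept in pairs 1 and 2. The Spearman correlation of the log2 ratio with length across genes was -0.551, -0.568 and -0.182 in pairs 1, 2 and 3. Between libraries of 1 genotype it was 0.278 for WT replicate 2 over replicate 1 and -0.125 for cmd1 KO replicate 2 over replicate 1. Abundance sorted the ratios too, in 5 equal classes by mean log2 CPM over all 6 libraries. The cmd1 KO values enter both the classes and the ratios, so part of this order can be built in. Classes on WT alone were not made. With TMM scaling the medians of the lowest class were -0.42, -0.55 and -0.22 in pairs 1, 2 and 3. Those of the highest class were 0.51, 0.70 and 0.24. Length and abundance were not separated.

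**Figure D2:**
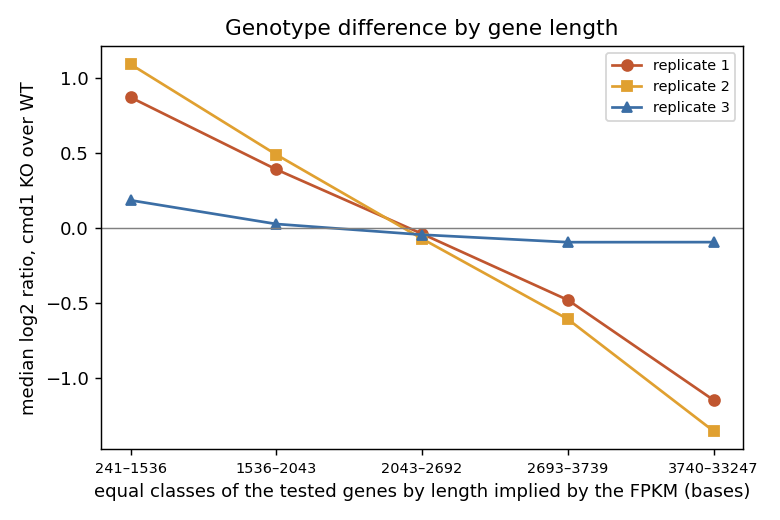
Median log2 ratio of cmd1 KO over WT with TMM scaling (vertical axis) in 5 equal classes of the tested genes by length in bases (horizontal axis), with 1 line per same-numbered pair. The medians run from 0.87 to -1.15 in replicate 1, from 1.09 to -1.36 in replicate 2 and from 0.18 to -0.10 in replicate 3, and library sizes alone put those of the shortest class at -0.48, -0.32 and -0.13.

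A block of neighbouring genes near the start of chromosome 17 was far lower in cmd1 KO in replicates 1 and 2 and level with WT in replicate 3. The block spanned 900712 to 1128215 on chromosome 17 (v5.5) and held 20 tested genes, with median log2 ratios of -2.89, -3.18 and 0.07 in pairs 1, 2 and 3. Of the 20, 16 fell and 3 rose in the edgeR test within replicates 1 and 2, and the genotype effect of 19 differed from that in replicate 3. Of all 10878 tested genes, 4117 fell and 3736 rose in the former test, and the interaction test marked 50.7%. The block was picked for low values in replicates 1 and 2, which both tests use, so these counts are no separate evidence. The 23 gene models of the whole block with at least 100 counts in WT replicates 1 and 2 had a median of 10.5% of the WT level in cmd1 KO replicates 1 and 2 with TMM scaling (range 0% to 469%, 5 of them over 50%), and of 102% in replicate 3 (22.6% to 944%). With library sizes alone the median in replicates 1 and 2 was 4.05% (0% to 181%). The core of the block, from 971632 to 1071247, was picked by windows of 11 genes for its low running median and held 12 tested genes. The 13 core gene models with that WT count had a median of 6.53% of the WT level in cmd1 KO replicates 1 and 2 with TMM scaling (range 0% to 29.4%), and of 101% of WT in replicate 3 (46.3% to 167%). With library sizes alone these medians were 2.53% (0% to 11.3%) and 82.1%. The block stood out in a scan of running medians over 21 genes after removal of the length trend, at p = 0.001 genome-wide, the smallest that 1000 permutations of the gene order can give. With library sizes alone its medians were -4.23, -4.51 and -0.25. The scan and its window were chosen after the data were seen. The same scan of replicate 3 marked 1 block, higher in cmd1 KO, beside this one on chromosome 17. It ran from 837449 to 873538 and held 4 tested genes (p = 0.012 genome-wide, permutations of the gene order). Its median log2 ratios were -0.89, -0.61 and 0.60 in pairs 1, 2 and 3.

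**Figure D3:**
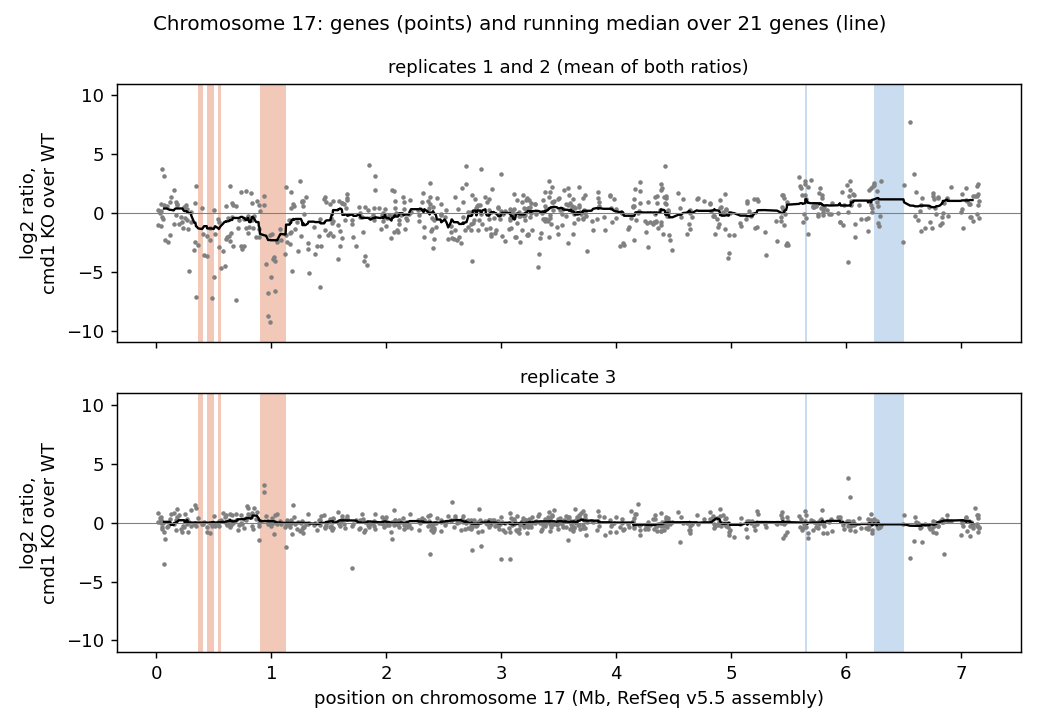
Log2 ratio of cmd1 KO over WT for each tested gene (grey points, TMM scaling) along chromosome 17 in Mb, with the running median over 21 genes after removal of the length trend (black line), for the mean of pairs 1 and 2 (top) and for pair 3 (bottom). Red bands mark blocks below and blue bands blocks above the permutation limits of -1.26 and 1.16 in replicates 1 and 2, and the widest red band starts at 900712, where the line of replicate 3 stays near 0. Library sizes alone turn the medians of the blue bands to below 0.

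The authors' deposited table gave the comparison as lower expression of most genes in cmd1 KO. Of 17736 genes, 9385 had an unadjusted p under 0.05 in the authors' deposited table, of which 9112 were lower and 273 higher in cmd1 KO. The median log2 fold change in the authors' deposited table was -1.22, and 84.9% of genes were lower. After Benjamini-Hochberg adjustment of the p-values in the authors' deposited table, 0 genes passed 0.05, the smallest adjusted value being 0.0541, and 9620 passed 0.1. The values of the authors' deposited table were recovered to within 1.87e-05 in log2 fold change and 3.05e-07 in p by an edgeR quasi-likelihood fit on library sizes alone with a term for replicate 3. The same fit with TMM scaling gave 2986 genes higher and 2836 lower at an unadjusted p under 0.05, a median log2 fold change of -0.06, and 0 genes after adjustment.

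**Figure D4:**
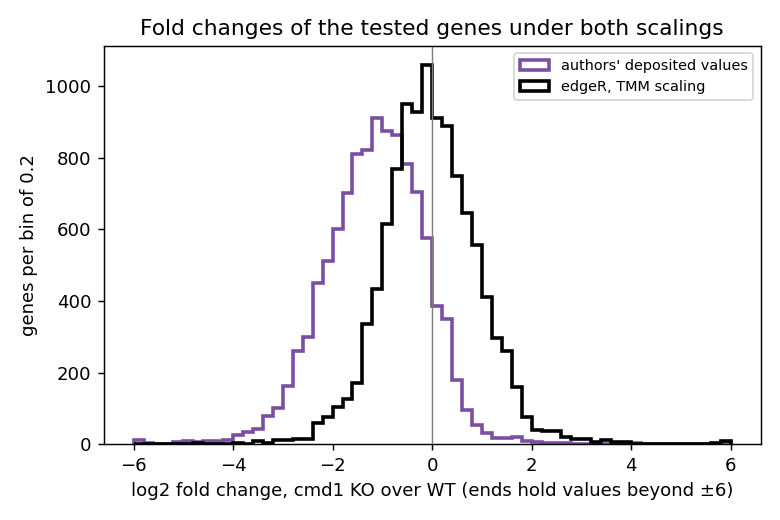
Number of tested genes per bin of 0.2 (vertical axis) by log2 fold change of cmd1 KO over WT (horizontal axis), for the values in the authors' deposited table (purple) and for edgeR with TMM scaling over all 6 libraries (black). The black outline is centred near 0, with 52.5% of genes lower, and the purple outline is shifted to lower values.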

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

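The tests in this part were chosen after the results they concern were seen, except that the bounds for the correlation after removal of the length trend and for the recount without the most abundant genes were set before those values were computed.

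The genotype effect differed between replicate 3 and replicates 1 and 2 in 5510 genes by the edgeR interaction test, 2969 more positive and 2541 more negative in replicate 3 with TMM scaling, and 6398 and 633 with library sizes alone. A length-dependent difference between libraries was argued against as the whole cause, since the correlation between the pairs 1 and 2 mean and pair 3 was 0.073 before and 0.024 after the length trend was removed. A second library of the WT replicate 3 culture under the mutant label was argued against too: 20 genes had at least 100 counts in WT replicate 3 and at most 3 in cmd1 KO replicate 3, against 0 such genes between WT replicates 1 and 2 and 0 between cmd1 KO replicates 1 and 2. A different culture state, a different mutant clone or a separate library batch in replicate 3 may each have played a part, and with 1 library per genotype in replicate 3, and no batch in the labels, these were not tested. The level of CMD1, which would check the genotype labels, was not analysed here.

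In the chromosome 17 block from 900712, 19 of 20 tested genes had a genotype effect in replicates 1 and 2 that differed from replicate 3. Among all tested genes the share was 50.7%, and the choice of the block for low values in replicates 1 and 2 favoured a high count. Removal of the length trend took the block median in replicates 1 and 2 from -2.97 to -2.33, with 0.14 in replicate 3 afterwards. The block was picked for low values after that removal, so a median far below 0 was all but fixed in advance. These medians therefore cannot weigh gene length as a cause. The lengths themselves can: the block's tested genes had a median length of 2055 bases. The class of 2043 to 2692 bases had median log2 ratios of -0.04 and -0.07 in pairs 1 and 2, and the longest class -1.15 and -1.36. The block medians of -2.89 and -3.18 lay far below these, which argues against the general length trend as the whole cause. Loss of the whole core from the genomes of cmd1 KO replicates 1 and 2 was left undecided: 38.5% of its gene models (5 of 13) kept over 10% of the WT level with TMM scaling but 15.4% (2 of 13) with library sizes alone, and reads shared with copies elsewhere, which could leave such a residue, were not tested. Loss of a part stays open too: with TMM scaling the 3 neighbouring gene models from 971632 to 990183 were at 0%, 0.506% and 0% of WT in cmd1 KO replicates 1 and 2, and at 114%, 90.9% and 102% in replicate 3. Silencing of the region, a rearrangement, or a strain difference between the cultures may equally apply and were not tested.

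Most genes were lower in the authors' deposited fold changes, and a larger share of counts in a few abundant genes may account for part of this. With the 200 most abundant genes taken out of the library totals, 64.7% of the tested genes were lower in cmd1 KO, against 89.0% with them in. Length was left undecided: the shortest of 5 length classes still had a median of -0.30 in the authors' deposited table, and the longest had -1.91. Neither value reached a bound that would settle it, and without an added RNA standard a smaller amount of RNA per cell cannot be told apart from a larger share in a few genes.

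The interaction test marked 50.7% of all tested genes (5510 of 10878). Close to that share, it marked 4 of 6 tested genes in the chromosome 17 block from 441728 to 505369, with medians of -2.08, -2.15 and -0.23 in pairs 1, 2 and 3. It marked 5 of 9 in the chromosome 4 block from 728498 to 837524, with medians of 1.39, 2.94 and 0.70, or 0.05, 1.53 and 0.39 with library sizes alone. It marked 7 of 10 in the chromosome 17 block from 6243858 to 6506738, with medians of 0.83, 0.75 and -0.18, or -0.53, -0.67 and -0.49 with library sizes alone. The chromosome 4 block was marked neither with windows of 11 or 41 genes nor with the length trend kept. Windows of 11 genes marked neither of these chromosome 17 blocks, and with the length trend kept the one from 6243858 was not marked. The one from 441728 then fell in a wider lower block, from 344284 to 579876 with 19 tested genes. Its lowest running median was -2.21, against -2.40 for the block then found from 936512 to 1150245. Windows of 41 genes marked wider blocks over both, from 401558 to 543237 and from 6007240 to 6657794. Cre08.g359567 differed between replicate 3 and replicates 1 and 2 at an adjusted p of 0.0137 in edgeR, with log2 ratios of -2.53, -2.87 and -1.47 in pairs 1, 2 and 3.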

How the results depend on the processing

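The scalings other than TMM in edgeR, the fit within replicates 1 and 2, the term for replicate 3, filterByExpr and DESeq2 with the block were chosen after the data were seen. The count of 0 genes past adjusted p in edgeR was unchanged with the replicate block, with either FPKM filter or none, with thresholds of 0.01 and 0.1, and with each of the other scalings, and the pairing changed no call in edgeR or limma. Counts of genes higher, lower and past 2-fold were 412, 276 and 667 with DESeq2, 1082, 790 and 1829 with DESeq2 and the replicate block, 3736, 4117 and 4871 within replicates 1 and 2, and 629, 8487 and 5187 with limma array weights, whose estimation stopped before convergence. Leaving out 1 library in turn gave 0 to 1974 higher, 0 to 2255 lower and 0 to 3730 past 2-fold, and all counts above 0 came from leaving out cmd1 KO replicate 3. The cause of these differences between tools was not tested. The share of tested genes lower in cmd1 KO, 52.5%, was 51.3% at a filter of 5 FPKM, 53.1% with the replicate block, 48.4% with DESeq2, 49.6% with DESeq2 and the block, 48.3% with RLE, 56.9% with upper quartile scaling, 53.1% with the term for replicate 3 and 51.9% with filterByExpr, and 45.8% to 56.0% with 1 library left out. Values scaled on library size put it far higher, through that scaling itself: 88.5% in edgeR, 89.2% with the replicate 3 term, and in limma 88.9% on log2(FPKM + 1), 89.0% and 88.9% at pseudocounts of 0.1 and 0.5, 92.3% as TPM, 88.9% without trend, 88.9% robust, 88.8% with array weights, 88.9% with the block, 87.5% unfiltered and 82.1% at 5 FPKM. limma with TMM factors gave 46.0% and with quantile normalisation 48.6%. The interaction count of 5510 was 2797 and the count within replicates 1 and 2 was 3721 at a filter of 5 FPKM, where fewer genes were tested; leaving out 1 of those libraries gave 4506 to 5780 and 6708 to 7563. The lowest running median of the chromosome 17 block, -2.31, was -4.68 with windows of 11 genes and -1.77 with windows of 41, as narrower windows average fewer genes outside the core. The 4 named genes reversed in 0 of their alternatives and each passed 0.05 in 5, with log2 differences of 0.77 to 2.78 for Cre01.g009350, 0.37 to 1.91 for Cre11.g478100, -2.84 to -0.95 for Cre09.g411500 and -3.33 to -0.72 for Cre08.g359567. These genes were picked for separated groups and a small p in the main fit, so a reversal was unlikely from the start. Planned list tests and leave-one-out fits in limma were not run. Simulated 4-fold changes were recovered by edgeR for 0% of genes with the spread of all 6 libraries, and for 99% with that of replicates 1 and 2, in 2 libraries against 2. DESeq2 recovered 40% with the spread of all 6 libraries. The calls thus depended on the spread and on the test used, and depth was not varied.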

Other observations

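The near-zero rules, the comparison of WT replicates and the scan in this part were chosen after the data were seen. The edgeR fit on all 10 splits of the libraries was planned before, while its bound, the counts at an unadjusted p and the comparison of splits that part the pairs were chosen after. In 29 genes both WT replicates 1 and 2 held at least 100 counts and both cmd1 KO replicates 1 and 2 at most 3, out of 12044 genes with that WT count. Of the 29, 7 lay on chromosome 17, and 5 of those 7 in the lower blocks of that chromosome described above, so that count is no separate evidence. In cmd1 KO replicate 3, 15 of the 29 held at least 50 counts, 17 lay within 2-fold of WT replicate 3, and 3 held at most 3 counts. The last 2 counts both include Cre15.g636550, which had 0 counts in both libraries of replicate 3. Some of the 29 were also low in WT replicate 3, such as Cre12.g556000 at 3 counts and Cre10.g433500 at 6. The same rule with the genotypes exchanged gave 7 genes. The rule uses raw counts, and the median count per gene was 79 and 60 in cmd1 KO replicates 1 and 2, against 263 and 250 in WT. It therefore favours genes near 0 in cmd1 KO, and the 29 and the 7 are not a like comparison. With other limits, at least 50 counts in both cmd1 KO replicates 1 and 2 and at most 2 in WT replicates 1 and 2, there were 12 genes, 3 of them on unplaced scaffolds. In cmd1 KO replicate 3, 8 of the 12 held at most 3 counts and 0 held at least 50.

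The WT cultures also differed among themselves. Between WT replicate 1 and WT replicate 3, 26 genes held at least 100 counts in replicate 1 and at most 3 in replicate 3, and 32 the reverse. With windows of 41 genes the scan of replicates 1 and 2 also marked, among others, a block of 22 tested genes on chromosome 5 from 368373 to 650890, with a highest running median of 1.06, that windows of 21 genes did not mark.

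All 10 splits of the 6 libraries into 3 and 3 gave 0 genes at an adjusted p of 0.05 in edgeR, the highest of the other splits being 0, and 10 splits are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1952 genes and the highest of the others 2750, from WT replicate 1 with cmd1 KO replicates 1 and 2 against the rest. Among the 4 splits that part all 3 pairs, the others gave 1051, 0 and 5.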
